A study of Mus musculus with 6 samples.

How the data were processed

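Liver RNA for 3 libraries of the scramble plasmid and 3 of the shBicd2 plasmid was purified with Trizol and checked on a Bioanalyzer, libraries were made with a TruSeq RNA kit, and sequencing was on an Illumina NovaSeq, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3 on mm10, per the submitters' processing notes. The annotation, the trimming, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The deposited values are FPKM, fragment counts scaled to the gene's length and the library's total counted reads, with 1 column per library and 14669 rows. No scaling between libraries beyond the total is stated. Tested on the values, every gene has a value above 0 in all 6 libraries, so genes at 0 in any library were not analysed here. Of the symbols, 8 stand on more than 1 row (18 rows), and these rows were kept apart.

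The column names give the group but not which labelled replicate a column is. Columns were therefore used as replicates of their group with no replicate number, and there were 0 columns of other samples.

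FPKM hold no counts, but a gene's values step in multiples of what 1 read is worth. With exon lengths from GENCODE M21 (GRCm38) for the 14556 genes matched, the smallest depth at which low values came out whole was taken for each library. It was 17.79, 17.93 and 16.03 M reads in Sc3, Sc4 and Sc5 and 18.27, 16.62 and 18.93 M reads in sh1, sh3 and sh6. At these depths 98.9% to 99.8% of the values below 50 reads of single-exon genes lay within 0.02 of a whole read, and 97.5% to 97.7% of those of multi-exon genes. A depth wrong by a factor of 1.01 gave 10.2% to 15.4% for single-exon genes. In all 6 libraries 14279 genes (98.1%) were whole. FPKM divides by length and depth, so a gene of few reads has coarse steps, and a few abundant genes can shift all the others: the 10 highest genes held 24.4% to 25.3% of all FPKM in scramble and 26.1% to 29.4% in shBicd2.

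Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 6 libraries were kept (10152 genes). A fold change is on the log2(FPKM + 1) scale, shBicd2 minus scramble, which understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with two-sided p-values adjusted by Benjamini-Hochberg over the tested genes and a threshold of 0.05. Gene lists from textbook knowledge (38 lists, 959 entries, of which 918 were found in the table) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists with at least 5 tested genes. The same lists were run with an estimated correlation and with fry. List members were also counted when adjusted over the list alone. Single values and library scores were compared by exact two-sided permutation, for which 0.1 is the smallest p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

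The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named Bicd2 first, then the genes past the threshold with the largest changes in each direction. As none passed, the 5 genes of smallest p in each direction were named, without gene models lacking a proper symbol, pseudogenes and immune receptor segments. From each list it named up to 4 members past the threshold or, where none passed, the 2 of smallest p. Some genes that the rule names are not reported here. A fixed panel (Bicd1, Tnf, Ifng, Il6, Il1b, Il4, Cxcl9, Cxcl10, Ccl2, Saa1, Socs3, Tnfrsf1a, Fas, Cdkn1a and Alb) is given whatever its result. Atf3, Jun, Ndrg1, Cyp7a1, ND1 and Stab2 were chosen after their values were seen.

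The alternatives set before the data were examined were pseudocounts of 0.1 and 0.01, no filter on low values, a mean FPKM of at least 5, the TPM scale, median-of-ratios size factors, quantile normalization, eBayes without trend or robust, array weights, other thresholds, other set tests, a replicate block, and leaving out each library in turn. Limma's voom on the recovered reads was added after the data were seen, on 9942 genes whose values were whole in all 6 libraries.

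The steps were tested on simulated data with the real genes' means, with 200 of 9942 genes changed in each of 5 runs. Each gene's spread was set midway between its own estimate and that of the median gene, and genes were drawn independently. A shift of a whole library was therefore not simulated, and the rates may not hold for the real data. With spreads taken from both groups, 31.4% of the 2-fold and 92.2% of the 4-fold changes were recovered at an adjusted p of 0.05. With the spread of the scramble group alone it was 84.0% and 98.2%. There were 8.8 and 8.6 false calls per run. Of 100 unchanged lists of independent genes, 1.4 fell below an unadjusted p of 0.05.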

Results

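Liver RNA was profiled in 6 libraries from 8-week-old wild-type male C57BL/6J mice. Each mouse had received 25 µg of plasmid in 2.5 ml of saline by hydrodynamic injection, in which a large volume given quickly into a vein carries DNA into liver cells. The plasmid encoded a short hairpin RNA against Bicd2 or a scrambled control hairpin. On day 3 the mice were given concanavalin A (ConA) intravenously at 15 mg/kg, and livers were taken 6 h later. ConA is a plant lectin that activates T cells and gives an acute hepatitis driven by cytokines. Bicd2 encodes an adaptor that links cargo to the dynein motor on microtubules. There were 3 libraries per group, called Sc3, Sc4 and Sc5 (scramble) and sh1, sh3 and sh6 (shBicd2) here. All of the mice had been given ConA, so the data hold the difference between plasmids during hepatitis and not the response to ConA itself. The depth recovered from the steps in the values ran from 16.03 M reads (Sc5) to 18.93 M reads (sh6), and the depths of the groups overlapped. The labels do not say that each library came from a separate animal. The p-values other than camera's therefore measure only the spread between these samples, which may be technical. Camera's p-values compare a list's genes with the other tested genes. With the preset correlation they take a list's genes as nearly independent, so they do not measure the spread between libraries.

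The first question was whether the targeted transcript was lower. Bicd2 (GRCm38 chromosome 13, 49341585 to 49387026, plus strand) was at 4.14, 3.43 and 3.13 FPKM in Sc3, Sc4 and Sc5. It was at 3.62, 2.57 and 2.97 FPKM in sh1, sh3 and sh6. The means were 3.57 ± 0.518 (SD, n = 3) and 3.05 ± 0.526 (SD, n = 3) FPKM, a difference of 14.4% of the scramble mean in the direction of a knockdown. The groups overlapped, and the difference was within the spread between libraries (exact two-sided permutation p = 0.4, where 0.1 is the smallest p that 3 against 3 can give). In the limma fit its log2 fold change was -0.17 ± 0.16 (SE), with an adjusted p of 0.624. Between 270 and 465 reads stood behind each value. A lower Bicd2 level was therefore not detectable in whole liver, and in sh1 it lay above the scramble mean. The groups below are those of the labels, and "shBicd2" means the libraries labelled so.

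**Figure D1:**
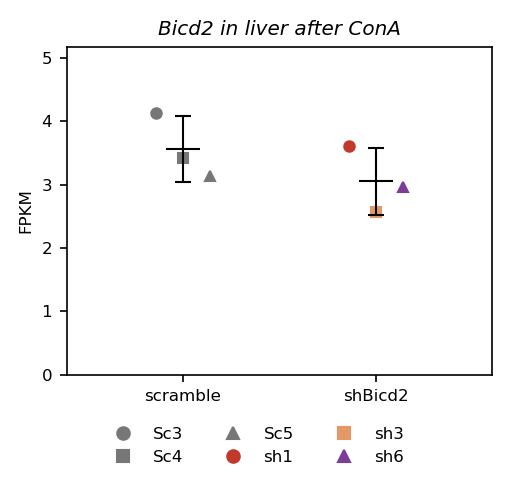
Bicd2 level (FPKM, vertical axis) in each library of the scramble and shBicd2 groups; points are libraries, horizontal bars are means and error bars are SD (n = 3). The scramble libraries lie between 3.13 and 4.14 FPKM and the shBicd2 libraries between 2.57 and 3.62 FPKM, so the groups overlap.

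Bicd1, the close relative of Bicd2, was at 0.0657, 0.0407 and 0.0798 FPKM in the scramble libraries and at 0.002, 0.0066 and 0.0212 FPKM in the shBicd2 libraries. These values rest on 1 to 35 reads, and the gene was below the filter for testing. The list of dynein, dynactin, kinesin and BICD family genes had 30 tested members with a median log2 fold change of -0.12, and it did not pass the set test (adjusted p = 0.503); over the alternatives the median ran from -0.21 to -0.02. The members of smallest p were Dync1li1, a dynein light intermediate chain, at 9.87 ± 1.76 and 5.50 ± 1.54 FPKM (SD, n = 3; adjusted p = 0.204 in the limma fit), and Dynlt1b, a dynein light chain, at 2.35 ± 0.608 and 4.19 ± 0.755 FPKM (adjusted p = 0.204). Dynlt1b has near-identical copies, so its reads are uncertain.

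The second question was which genes differed between the shBicd2 and scramble livers. None of the 10152 genes tested passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.109. At an unadjusted p below 0.05 there were 1593 genes, against 508 by chance. Leaving out 1 library gave from 832 (without Sc5) to 2501 (without sh3) such genes, and array weights gave 4186. Limma's voom on the recovered reads also called 0 genes, with 1597 at an unadjusted p below 0.05. The groups did not overlap for 2474 genes (24.4%), where chance gives 10%. Of the 1593 genes, 302 were higher and 1291 lower in shBicd2. This split moved with the scaling between libraries: it was 633 higher and 874 lower with median-of-ratios size factors, 693 and 812 with quantile normalization, and 181 and 1768 on the TPM scale. It also moved without sh3 (961 higher and 1540 lower) and with array weights (1602 and 2584). Leaving out sh3 gave 289 genes past the threshold, 30 higher and 259 lower. Limma's array weights, which count a library less the more it departs from its group, gave 2709 genes, 850 higher and 1859 lower, with weights of 4.67 for sh6 and 3.01 for Sc3 against 0.18 for sh1 and 0.28 for sh3.

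The shBicd2 libraries differed more among themselves than the scramble libraries did. Across genes, which are not independent replicates, the correlation between scramble libraries was 0.981 to 0.988, and between shBicd2 libraries 0.905 to 0.963. Library sh1 stood apart, at 0.893 to 0.913 with the scramble libraries. On the first principal component, with 58.9% of the variance, sh1 was at 54.9, sh6 at 10.7 and sh3 at -14.5, inside the scramble range of -22.2 to -12.0.

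By smallest p, the genes lower in shBicd2 began with Ugt1a7c (chromosome 1, 88095062 to 88220002), a glucuronosyltransferase at 2.10 ± 0.153 FPKM in scramble and 0.219 ± 0.0692 FPKM in shBicd2 (SD, n = 3; limma adjusted p = 0.109). It shares exons with other genes of the Ugt1a cluster, so the split of reads among them is uncertain. Sowahb (log2 fold change -1.22 ± 0.13 SE), Itpripl2 (-1.003 ± 0.118), Srxn1 (-1.54 ± 0.19) and Basp1 (-1.55 ± 0.20) came next. Srxn1 encodes sulfiredoxin, which repairs oxidised peroxiredoxins. The shBicd2 values of these 5 genes all lay below the scramble values, and none passed (adjusted p from 0.109 to 0.152). Genes of small p that were higher in shBicd2 included the mitochondrial ND4L (2.68 ± 0.46), cyclin B1 gene Ccnb1 (1.17 ± 0.21, and 1.90 with a pseudocount of 0.01), Agmat (0.76 ± 0.14) and mitochondrial COX2 (1.05 ± 0.21). All shBicd2 values of these 4 genes lay above the scramble values, and none passed (adjusted p from 0.152 to 0.153). Without sh3, ND4L, Ccnb1, Ugt1a7c, Sowahb, Itpripl2, Srxn1 and Basp1 were past the threshold (adjusted p from 0.0278 to 0.0312).

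Of 38 gene lists fixed before the data were examined, 34 had at least 5 tested genes, and 17 passed camera with its preset correlation. Camera compares a list's genes with the other tested genes, and the median log2 fold change of all tested genes was -0.06. In that relative sense 8 lists were higher and 9 lower in shBicd2. Camera's direction also rests on the genes' test statistics and not on the median, so a list can point higher with a median near or below 0. After quantile normalization 4 lists were past the threshold as higher and 12 as lower. With the correlation estimated for each list, 0 of the 34 passed, and the smallest adjusted p was 0.172. The estimate was 0.677 for TNF and NF-kB targets, 0.679 for AP-1, 0.690 for hypoxia and 0.689 for cell cycle genes. For hepatocyte markers it was -0.005 and for stellate cell markers 0.016, against the preset 0.01. Calls with the preset correlation are thus too ready for lists of correlated genes. Fry, which asks only whether a list's genes move one way on balance, called 3 lists: hepatocyte markers, death receptor genes and stellate cell markers. Its form for changes in either direction called NRF2 oxidative stress genes (adjusted p = 0.00865), mitochondrial transcripts (0.0195) and hepatocyte markers (0.0350). Library scores, the mean centred log2 value of a list's genes, did not overlap between groups for 15 lists, or 9 with median-of-ratios size factors, against 3.4 by chance.

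**Figure D2:**
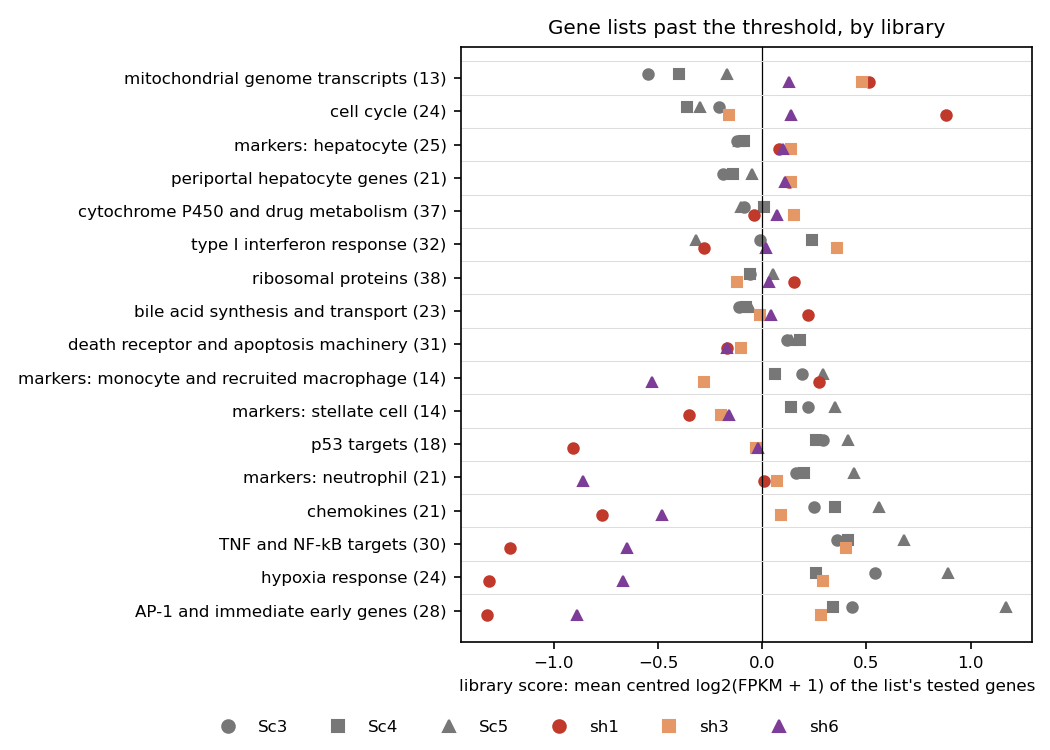
Library scores (mean centred log2(FPKM + 1) of a list's tested genes, horizontal axis) for the 17 lists past the threshold, with the number of tested genes in brackets; each point is a library (3 scramble in grey, 3 shBicd2 in colour), and there are no error bars. For the AP-1, hypoxia and TNF lists sh1 and sh6 lie far below the scramble libraries, while sh3 lies within or next to them.

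The lists of AP-1 and immediate early genes, TNF and NF-kB targets, and chemokines lay lower in shBicd2 livers, mainly in sh1 and sh6. All 28 tested AP-1 and immediate early genes had negative fold changes, with a median of -1.07 (camera adjusted p = 3.89e-09; adjusted p = 0.581 with an estimated correlation). Of these, 16 fell when adjusted over the list alone and 0 over all genes tested. The list's scores were -1.32, 0.28 and -0.89 in sh1, sh3 and sh6, against 0.34 to 1.17 in scramble. Dusp6 and Dusp5, phosphatases that switch off MAP kinases, had the smallest p in this list, with log2 fold changes of -1.16 ± 0.29 and -1.08 ± 0.29 (SE); that of Dusp5 was -1.80 with a pseudocount of 0.01. Atf3 and Jun, chosen after their values were seen, are stress-induced transcription factors. Atf3 was at 103 ± 52.1 FPKM in scramble and at 2.31, 49.1 and 6.74 FPKM in sh1, sh3 and sh6. Jun was at 114 ± 50.5 FPKM (SD, n = 3) in scramble and at 7.06, 72.3 and 22.1 FPKM in sh1, sh3 and sh6.

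TNF and NF-kB targets had a median of -0.91, with all 30 tested members negative (camera adjusted p = 2.24e-07; adjusted p = 0.652 with an estimated correlation). None of them passed when adjusted over the list alone or over all genes. Their scores were -1.21, 0.40 and -0.65 in sh1, sh3 and sh6, so sh3 lay inside the scramble range of 0.36 to 0.68. Irf1, an interferon-induced transcription factor, was at 103 ± 22.4 and 45.8 ± 15.6 FPKM (SD, n = 3), and Cd83 at 1.64 ± 0.470 and 0.415 ± 0.248 FPKM, with sh3 the highest at 0.702 FPKM.

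Chemokines had a median of -0.81, with 18 of 21 tested members negative (camera adjusted p = 0.00827; adjusted p = 0.341 with an estimated correlation). Of these, 5 fell when adjusted over the list alone and 0 over all genes. Scores were -0.77, 0.09 and -0.48 in sh1, sh3 and sh6, all below the scramble scores of 0.25 to 0.56. Cxcl9 (chromosome 5), which draws T cells through CXCR3, was at 1268 ± 109 FPKM in scramble and 513 ± 154 FPKM in shBicd2 (SD, n = 3), a log2 fold change of -1.35 ± 0.25 (SE; limma adjusted p = 0.152). Cxcl10, a ligand of the same receptor, was at 316 ± 117 FPKM in scramble and at 18.2, 174 and 28.0 FPKM in sh1, sh3 and sh6 (adjusted p = 0.199). Ccl2, which draws monocytes, was at 86.1 ± 27.7 FPKM in scramble and at 4.62, 81.7 and 15.0 FPKM in sh1, sh3 and sh6 (adjusted p = 0.308). The chemokine call was lost without sh6 (adjusted p = 0.101), and with no filter on low values its median was -0.28. Cxcl9, Cxcl10, Ccl2, Irf1, Cd83, Atf3 and Jun were past the gene threshold without sh3 (adjusted p from 0.0278 to 0.0435).

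**Figure D3:**
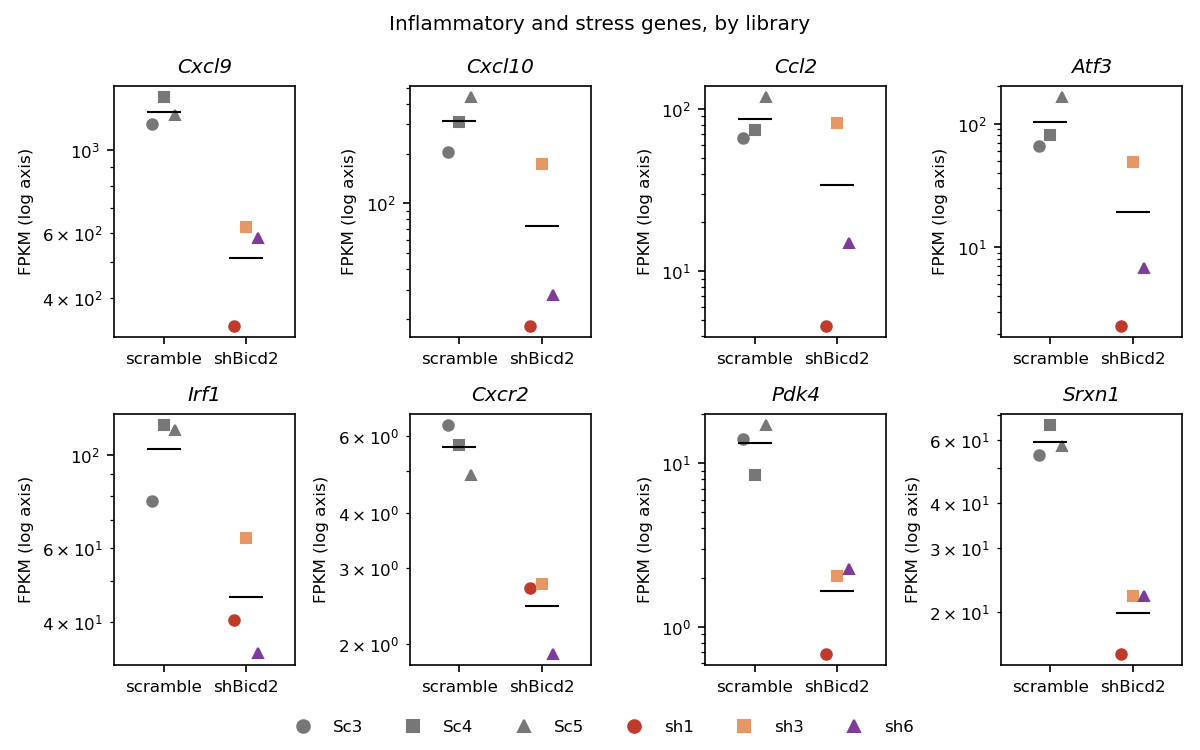
FPKM (log axis) of 8 inflammatory and stress genes in each library of the scramble and shBicd2 groups; points are libraries and horizontal bars are arithmetic means of 3, with no error bars drawn. Cxcl9 lies between 337 and 622 FPKM in shBicd2 and between 1174 and 1388 FPKM in scramble, while the shBicd2 libraries are spread widely for Ccl2, from 4.62 to 81.7 FPKM.

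The cytokines themselves were low in the tissue. Ifng was at 1.74, 1.77 and 0.578 FPKM in scramble and at 0.338, 0.418 and 0.0816 FPKM in shBicd2, from 2 to 41 reads. Its groups did not overlap, but its mean was under the filter and it was not tested in the fit (exact permutation p = 0.1, the smallest possible). Il6 was at 0.492 ± 0.268 and 0.106 ± 0.145 FPKM, the latter mainly from sh3 (0.273 FPKM), and Il4 at 0.451 ± 0.202 and 0.378 ± 0.0591 FPKM (SD, n = 3), both overlapping and untested. Tnf was at 2.79 ± 0.428 FPKM in scramble and at 1.44, 3.71 and 1.51 FPKM in sh1, sh3 and sh6, also overlapping (adjusted p = 0.618). The list of T cell derived and inflammatory cytokines did not pass (median -0.22, adjusted p = 0.7503), except with array weights (median -0.37, adjusted p = 0.0205), and without sh6 its median was -0.04. Its members of smallest p were Il1b and Il18. Il1b was at 4.98 ± 0.738 FPKM in scramble and 1.03, 4.23 and 1.83 FPKM in sh1, sh3 and sh6. Il18 was at 3.81 ± 0.634 FPKM in scramble and 11.7, 6.01 and 4.87 FPKM in sh1, sh3 and sh6. Interferon gamma targets missed the threshold (median -0.22, camera adjusted p = 0.0625), although their scores did not overlap between groups. That list passed with size factors (adjusted p = 0.0435), quantile normalization (0.00216) or array weights (0.0109), and without Sc3 (0.0249), Sc5 (0.000721), sh1 (0.0151) or sh3 (0.0403), and its median ran from -0.40 without Sc5 to -0.10 with no filter on low values. In that list 4 genes fell when adjusted over the list alone and 0 over all genes. Gbp10, an interferon-induced GTPase with close paralogs, was at 67.5 ± 1.44 and 34.0 ± 5.33 FPKM (SD, n = 3). Type I interferon genes went slightly the other way, with a median of 0.07 and 20 of 32 members positive (camera adjusted p = 0.0183; adjusted p = 0.810 with an estimated correlation). None of them passed when adjusted over the list alone. Isg15 had a log2 fold change of 0.98 ± 0.30 and Dhx58 of 0.52 ± 0.22 (SE). Dhx58 was at 5.86 FPKM in sh1, next to the scramble range of 5.56 to 5.66 FPKM, and at 9.31 and 11.1 FPKM in sh3 and sh6; its log2 fold change was 0.34 without sh6 and 0.83 with array weights. Scores of this list overlapped, with sh1 at -0.28, sh3 at 0.36 and sh6 at 0.02 against -0.32 to 0.24 in scramble. Its call was lost without Sc5 (adjusted p = 0.364), without sh3 (adjusted p = 0.987) and with quantile normalization, array weights or a mean FPKM of at least 5, and its median, which ran from -0.04 to 0.19 over the alternatives, turned negative (-0.01) on the TPM scale.

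Acute phase genes did not pass as a list (median -0.21, adjusted p = 0.503), although they did with quantile normalization (adjusted p = 0.0011) and array weights (0.049). Over the alternatives the median ran from -0.30 to -0.09. Crp, C-reactive protein, was at 359 ± 65.6 and 150 ± 21.3 FPKM (SD, n = 3). Il1rn, the interleukin 1 receptor antagonist, was at 45.2 ± 4.91 FPKM in scramble and at 4.74, 37.1 and 10.6 FPKM in sh1, sh3 and sh6, so sh3 carried most of its shBicd2 mean (log2 fold change -2.50 without sh3 and -1.13 without sh1). Crp fell when adjusted over the list alone, the only member to do so, and 0 members passed over all genes. Saa1, a major serum amyloid whose reads are shared with close copies, was at 2117 ± 292 FPKM in scramble and at 3898, 1502 and 1705 FPKM in sh1, sh3 and sh6. Socs3, an inhibitor of cytokine signalling, was at 48.2 ± 4.33 FPKM in scramble and at 21, 74.7 and 42.1 FPKM in sh1, sh3 and sh6.

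Hypoxia response genes had a median of -1.01 with all 24 tested members negative (camera adjusted p = 3.83e-08; adjusted p = 0.581 with an estimated correlation). Of these, 9 fell when adjusted over the list alone and 0 over all genes. Scores were -1.31, 0.29 and -0.67 in sh1, sh3 and sh6, with sh3 inside the scramble range of 0.26 to 0.89. Hk1, a hexokinase, was at 4.10 ± 0.605 and 1.40 ± 0.545 FPKM, and P4ha2, a collagen prolyl hydroxylase, at 5.60 ± 1.43 and 2.01 ± 0.402 FPKM (SD, n = 3). Ndrg1, chosen after its values were seen, was at 25.3 ± 7.46 FPKM in scramble and at 1.004, 9.87 and 2.28 FPKM in sh1, sh3 and sh6.

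Genes of the death receptor and apoptosis machinery had a median of -0.21, and 26 of 31 were negative (camera adjusted p = 0.0277; adjusted p = 0.254 with an estimated correlation; fry adjusted p = 0.00955). Their scores of -0.17, -0.10 and -0.17 in sh1, sh3 and sh6 lay below the scramble scores of 0.12 to 0.18. None passed when adjusted over the list alone. Mcl1, a survival factor, was at 67.6 ± 4.88 and 46.9 ± 6.10 FPKM (SD, n = 3). Fas, a death receptor, was at 23.5 ± 1.27 and 24.1 ± 5.03 FPKM, and the TNF receptor gene Tnfrsf1a at 73.2 ± 1.95 and 67.5 ± 13.2 FPKM. The p53 targets had a median of -0.55, with 14 of 18 negative (camera adjusted p = 0.0183; adjusted p = 0.652 with an estimated correlation), and 2 fell when adjusted over the list alone. Pmaip1, which encodes the death-promoting protein NOXA, was at 2.95 ± 0.672 and 1.10 ± 0.375 FPKM, and Mdm2, the inhibitor of p53, at 24.9 ± 5.41 and 12.7 ± 2.72 FPKM. Cdkn1a, the cell cycle inhibitor p21, was at 48.7 ± 9.10 FPKM in scramble and at 2.48, 56.0 and 35.9 FPKM in sh1, sh3 and sh6. The p53 score was -0.91 in sh1, against -0.03 in sh3 and -0.02 in sh6, and without sh1 the median was -0.23 and the call was lost (adjusted p = 0.213). The death receptor call was lost without Sc4 (adjusted p = 0.0756) or sh6 (adjusted p = 0.133), and both calls were lost at a mean FPKM of at least 5 (adjusted p = 0.0703). The p53 call was lost with array weights, and the death receptor median was -0.13 with size factors.

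The remaining stress lists did not pass camera in the main setting. Heat shock genes had a median of -0.23 (adjusted p = 0.133), with scores that did not overlap and 4 members that fell when adjusted over the list alone. Hspa1a and Hspa1b, near-identical HSP70 genes whose reads cannot be told apart with certainty, had log2 fold changes of -1.84 ± 0.35 and -1.79 ± 0.29 (SE); that of Hspa1a was -2.81 with a pseudocount of 0.01. The NRF2 oxidative stress list had a median of -0.06 (adjusted p = 0.823), where Srxn1 fell when adjusted over the list alone. Fry's test for changes in either direction called the NRF2 list (adjusted p = 0.00865). Pgd, of the pentose phosphate pathway, was at 19.2 ± 2.37 and 12.9 ± 0.213 FPKM (SD, n = 3). Endoplasmic reticulum stress genes had a median of 0.05 and a mean of -0.05 (adjusted p = 0.730). Trib3 was at 6.51 ± 1.75 and 2.45 ± 0.950 FPKM and Asns, asparagine synthetase, at 6.81 ± 1.47 and 3.63 ± 1.61 FPKM. Heat shock genes passed without sh1 (adjusted p = 0.0261) or with quantile normalization (0.0266), and endoplasmic reticulum stress genes passed as higher without sh1 (median 0.35, adjusted p = 0.000251) or with array weights (0.0156). Over the alternatives the medians ran from -0.34 to -0.15 for heat shock, -0.16 to 0.03 for NRF2 and -0.19 to 0.41 for endoplasmic reticulum stress genes.

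Markers of infiltrating myeloid cells were lower in shBicd2 livers, with the lowest scores in sh6. Neutrophil markers had a median of -0.59, with 18 of 21 negative (camera adjusted p = 0.0019; adjusted p = 0.652 with an estimated correlation), and 3 fell when adjusted over the list alone. Cxcr2, a chemokine receptor of neutrophils, was at 5.66 ± 0.738 and 2.45 ± 0.470 FPKM, and Ly6g at 3.31 ± 0.266 and 1.61 ± 0.314 FPKM (SD, n = 3). The neutrophil scores were 0.01, 0.07 and -0.86 in sh1, sh3 and sh6, against 0.16 to 0.44 in scramble. Monocyte and recruited macrophage markers had a median of -0.31, with 12 of 14 negative (camera adjusted p = 0.0437; adjusted p = 0.810 with an estimated correlation), and 3 fell when adjusted over the list alone. Chil3 was at 30.1 ± 3.01 and 14.1 ± 3.64 FPKM and Lgals3, galectin 3, at 23.7 ± 3.25 and 12.6 ± 2.65 FPKM. Monocyte scores were 0.27, -0.28 and -0.53 in sh1, sh3 and sh6, so sh1 lay within the scramble range of 0.06 to 0.29. Without sh6 both calls were lost, the neutrophil median was -0.38 (adjusted p = 0.340) and the monocyte median -0.06 (adjusted p = 0.693). The monocyte call was also lost without Sc5 (adjusted p = 0.0845), without sh3 (adjusted p = 0.111), at a mean FPKM of at least 5 and on the TPM scale, and its median without sh1 was -0.57. With array weights the neutrophil median was -1.03 and the monocyte median -0.61, and over all alternatives the monocyte median ran from -0.61 to -0.06.

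Stellate cell markers had a median of -0.38, and all 14 tested members were negative (camera adjusted p = 0.00252; adjusted p = 0.254 with an estimated correlation; fry adjusted p = 0.0237). Of these, 2 fell when adjusted over the list alone and 0 over all genes. Scores were -0.35, -0.20 and -0.16 in sh1, sh3 and sh6, below the scramble scores of 0.14 to 0.35. Timp1, an inhibitor of matrix metalloproteinases, was at 9.07 ± 0.847 and 4.36 ± 0.741 FPKM, and Lox, which crosslinks collagen, at 2.72 ± 0.942 and 0.667 ± 0.395 FPKM (SD, n = 3). At a mean FPKM of at least 5 the stellate median was -0.67. Kupffer cell markers passed only without sh1 (median -0.35, adjusted p = 0.0279) and not otherwise (median -0.10, adjusted p = 0.429); Adgre1, which encodes F4/80, was at 2.83 ± 0.839 and 1.44 ± 0.293 FPKM and Slc15a3 at 2.72 ± 0.0993 and 1.62 ± 0.441 FPKM. Sinusoidal endothelial markers had a median of 0.07 and a mean of -0.05 (adjusted p = 0.7503), and Cdh5 alone fell when adjusted over the list alone. Cdh5, VE-cadherin, was at 8.30 ± 1.48 and 4.20 ± 0.498 FPKM and Pecam1 at 4.27 ± 0.664 and 2.66 ± 0.394 FPKM, whereas Stab2, chosen after its values were seen, was at 3.09 ± 0.181 and 3.31 ± 1.02 FPKM. Cholangiocyte markers had 5 tested members and a median of -0.07 (adjusted p = 0.785), with Sox9 at 9.29 ± 2.92 and 4.92 ± 1.57 FPKM and Mmp7 at 2.72 ± 0.864 FPKM in scramble and 0.871, 1.014 and 3.02 FPKM in sh1, sh3 and sh6. Red cell markers, also 5, had a median of -0.25 while the set test pointed higher (adjusted p = 0.7503), with Hbb-bt at 9.34 ± 2.04 and 6.46 ± 3.13 FPKM and Klf1 at 0.876 ± 0.189 and 1.38 ± 0.290 FPKM. Over the alternatives the medians ran from -0.35 to 0.01 for Kupffer cell, -0.13 to 0.22 for endothelial, -0.56 to 0.17 for cholangiocyte and -0.44 to 0.33 for red cell markers. Lists for T, NK, B and dendritic cells had 2 to 4 genes above the filter and were not tested with it; with no filter on low values none of the 4 passed (adjusted p from 0.270 to 0.677). Their group mean scores were 0.03 and -0.03 for T cells, 0.03 and -0.03 for NK cells, 0.03 and -0.03 for B cells, and -0.01 and 0.01 for dendritic cells, scramble first. Only 3 of 22 T cell, 4 of 18 NK cell, 3 of 12 B cell and 2 of 14 dendritic cell markers reached a mean of 1 FPKM. Differences between lower values are pressed towards 0 on the log2(FPKM + 1) scale, so a change in these cells is not excluded.

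Hepatocyte markers were higher as a list in shBicd2 livers, with a median of 0.32 and 16 of 25 positive (camera adjusted p = 3.10e-06; adjusted p = 0.172 with an estimated correlation; fry adjusted p = 0.00585). None passed when adjusted over the list alone. Scores were 0.08, 0.14 and 0.10 in sh1, sh3 and sh6, above the scramble scores of -0.12 to -0.09, and the shBicd2 values of 14 members lay above all scramble values. Apoa1, the main protein of high-density lipoprotein, was at 3062 ± 155 and 4571 ± 431 FPKM, and Ttr, transthyretin, at 1703 ± 96.5 and 2425 ± 120 FPKM (SD, n = 3; limma adjusted p = 0.179 and 0.185). Alb, albumin, was at 17380 ± 3268 and 22210 ± 3691 FPKM, with overlapping groups (adjusted p = 0.397). The hepatocyte median was 0.18 after quantile normalization and 0.19 with array weights, and the list kept its call.

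**Figure D4:**
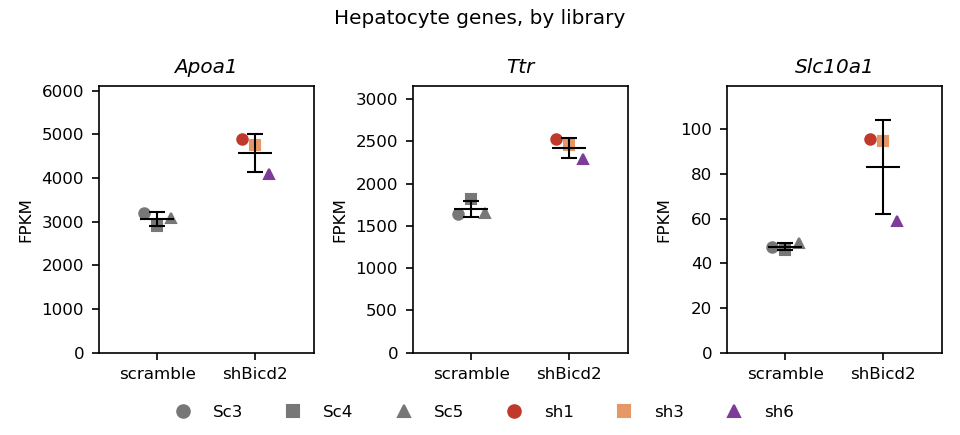
FPKM of 3 hepatocyte genes in each library of the scramble and shBicd2 groups; points are libraries, horizontal bars are means and error bars are SD (n = 3). For Apoa1, Ttr and Slc10a1 the shBicd2 libraries all lie above the scramble libraries, with Slc10a1 at 58.9 FPKM in sh6 and at 95.5 and 94.8 FPKM in sh1 and sh3.

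Periportal hepatocyte genes had a median of 0.20, with 17 of 21 positive (camera adjusted p = 0.0006; adjusted p = 0.233 with an estimated correlation), and their scores did not overlap. Hsd17b6 was at 8.79 ± 3.55 and 24.2 ± 7.97 FPKM and Aldh1b1, a mitochondrial aldehyde dehydrogenase, at 9.60 ± 1.37 and 22.2 ± 12.3 FPKM (SD, n = 3), highest in sh1 (36.2 FPKM). Cytochrome P450 and drug metabolism genes had a median of 0.18, with 25 of 37 positive (camera adjusted p = 0.000992; adjusted p = 0.254 with an estimated correlation). Scores of this list overlapped, with sh1 at -0.04 and scramble at -0.10 to 0.01. Cyp1a2 was at 209 ± 31.1 and 318 ± 47.2 FPKM and Cyp2a12 at 90.3 ± 2.91 and 123 ± 8.32 FPKM. Bile acid synthesis and transport genes had a median of 0.02 and a mean of 0.17, with 13 of 23 positive (camera adjusted p = 0.0346; adjusted p = 0.268 with an estimated correlation). Slc10a1, the bile acid importer NTCP, was at 47.4 ± 1.57 and 83.1 ± 20.9 FPKM, and Cyp39a1, an oxysterol hydroxylase, at 2.62 ± 0.248 and 4.34 ± 0.387 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis and chosen after its values were seen, was at 0.418 ± 0.130 FPKM in scramble and at 11.9, 0.447 and 2.898 FPKM in sh1, sh3 and sh6. None of the members of these 3 lists passed when adjusted over the list alone.

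Leaving out sh3 ended the periportal call (adjusted p = 0.0563), the P450 call (adjusted p = 0.158) and the bile acid call (adjusted p = 0.277). The bile acid call was also lost without Sc3 (adjusted p = 0.0544) or Sc4 (adjusted p = 0.0692), at a mean FPKM of at least 5, with size factors, with quantile normalization and with array weights, and its median turned negative on the TPM scale (-0.07) and without sh1 (-0.05) or sh3 (-0.02), with a range of -0.07 to 0.14 over the alternatives. Quantile normalization ended the P450 call (adjusted p = 0.0679) at a median of 0.23. The P450 median was 0.18 without sh3 and 0.11 at a mean FPKM of at least 5. The periportal median was 0.11 on the TPM scale, 0.24 without sh3 and 0.31 without sh6.

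Other metabolic lists did not pass. Without sh1 the lists for gluconeogenesis, fatty acid oxidation, pericentral genes and cholesterol synthesis were past the threshold (adjusted p from 0.000782 to 0.0318), with medians of 0.17, 0.11, 0.09 and -0.35, and with array weights fatty acid oxidation as higher (median 0.08, adjusted p = 0.03) and fatty acid synthesis as lower (median -0.39, adjusted p = 0.0267) were. Pericentral hepatocyte genes had a median of -0.18 while the set test pointed higher (adjusted p = 0.850); Lect2 was at 49.2 ± 7.52 and 66.1 ± 3.39 FPKM (SD, n = 3). Fatty acid oxidation and ketogenesis genes had a median of -0.02, with the test again pointing higher (adjusted p = 0.488). In that list Pdk4, a kinase that shuts down pyruvate dehydrogenase, was at 13.2 ± 4.40 and 1.66 ± 0.850 FPKM and fell when adjusted over the list alone, and Hadh was at 14.4 ± 0.777 and 21.7 ± 3.72 FPKM. Fatty acid synthesis genes had a median of -0.06 (adjusted p = 0.819), with the lipid droplet protein gene Plin2 at 289 ± 34.3 FPKM in scramble and 52.2, 73.8 and 184 FPKM in sh1, sh3 and sh6 and Dgat2, which makes triglyceride, at 185 ± 15.5 and 108 ± 35.0 FPKM. Cholesterol synthesis genes had a median of -0.06 with the test pointing higher (adjusted p = 0.864), and Idi1 was at 28.9 ± 7.62 and 15.0 ± 7.34 FPKM and Hsd17b7 at 20.5 ± 3.45 and 13.7 ± 6.25 FPKM. Gluconeogenesis and urea cycle genes had a median of 0.10 and a mean of -0.06 (adjusted p = 0.293). Got1 was at 235 ± 55.4 FPKM in scramble and at 53.6, 160 and 129 FPKM in sh1, sh3 and sh6, and Slc25a15 at 113 ± 16.9 and 68.8 ± 23.2 FPKM. Circadian clock genes had a median of -0.27 with the test pointing higher (adjusted p = 0.944), and 2 rose and 2 fell when adjusted over the list alone. Their scores did not overlap, at -0.06, -0.08 and -0.07 in sh1, sh3 and sh6 against 0.03 to 0.11 in scramble. A set test for a shared direction can miss a list whose members move both ways. Fry's test for changes in either direction did not call this list (adjusted p = 0.0898). A difference in time of day between the groups was not tested. Nr1d1, the clock repressor REV-ERB alpha, was at 43.6 ± 10 and 17.5 ± 3.98 FPKM. Over the alternatives the medians ran from -0.33 to 0.09 for pericentral, -0.11 to 0.11 for fatty acid oxidation, -0.39 to 0.09 for fatty acid synthesis, -0.35 to 0.27 for cholesterol synthesis, 0 to 0.19 for gluconeogenesis and -0.40 to -0.01 for circadian clock genes.

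Cell cycle genes were higher in shBicd2, above all in sh1. The median was 0.52 with 23 of 24 members positive (camera adjusted p = 9.54e-10; adjusted p = 0.551 with an estimated correlation), and 7 rose when adjusted over the list alone and 0 over all genes. Scores were 0.88, -0.16 and 0.14 in sh1, sh3 and sh6, above the scramble scores of -0.36 to -0.21. Cdc20, an activator of the anaphase-promoting complex, was at 2.04 ± 0.422 and 7.82 ± 3.30 FPKM, and Ccnb1 at 0.844 ± 0.230 and 3.2 ± 0.974 FPKM (SD, n = 3). Without sh1 the median was 0.26, and the list still passed. The median was 0.79 with a pseudocount of 0.1, 0.84 with 0.01 and 0.85 by voom, which was added after the data were seen.

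Transcripts of the mitochondrial genome were higher in shBicd2, with a median of 0.57 and all 13 positive (camera adjusted p = 1.24e-09; adjusted p = 0.254 with an estimated correlation). Of these, 7 rose when adjusted over the list alone and 0 over all genes. Scores were 0.51, 0.48 and 0.13 in sh1, sh3 and sh6, above the scramble scores of -0.55 to -0.17. They made up 9.59% to 11.3% of all FPKM in scramble and 12.3% to 14.6% in shBicd2. The 7 transcripts above 1000 FPKM had log2 fold changes of 0.31 to 0.64, and ND1, chosen after its values were seen, was at 4368 ± 739 and 5478 ± 953 FPKM (SD, n = 3). ND4L, at 91.0 ± 20.4 and 661 ± 349 FPKM, COX2, at 155 ± 10.7 and 328 ± 77.6 FPKM, and another 4 listed below 1000 FPKM have near-identical nuclear copies and are uncertain. The median was 0.35 after quantile normalization. Ribosomal protein genes had a median of 0.06, with 25 of 38 positive (camera adjusted p = 0.0423; adjusted p = 0.916 with an estimated correlation), overlapping scores and 0 members past the threshold over the list alone. Rpl5 was at 57.6 ± 3.61 and 48.0 ± 4.85 FPKM, and Rpl11 at 42.6 ± 3.28 FPKM in scramble and 65.1, 42.8 and 49.2 FPKM in sh1, sh3 and sh6. The ribosomal call was lost in 9 of 17 alternatives, among them those without Sc3, Sc4, sh1, sh3 or sh6 (adjusted p from 0.0506 to 0.186), and its median turned negative on the TPM scale (-0.03) and without sh1 (-0.03), with a range of -0.03 to 0.15 over the alternatives.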

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

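Voom was chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the numbers in the column names do not match the replicate numbers of the labels, so the planned replicate block was not run. Bicd2 was lower, and short of the threshold, in the 16 alternatives that test it (log2 fold change from -0.29 to -0.06); at a mean FPKM of at least 5 it is not tested. The count of genes past the threshold was 0 in all alternatives but array weights (2709) and, among those without 1 library, sh3 (range 0 to 289); array weights rest mainly on sh6 and Sc3. Gene lists past the threshold numbered 17 (12 to 23 without 1 library) and became 10 at a mean FPKM of at least 5, where fewer lists and genes are tested, 3 with fry and 0 with an estimated correlation. Lists with scores that do not overlap numbered 15, and 9 with size factors. The cause was not tested for the other changes. The AP-1, TNF, hypoxia, hepatocyte, stellate and mitochondrial lists kept their direction and call in the 17 alternatives that use the same set test, and the cell cycle list in the 16 that tested it. Among named genes, 66 gained a call with array weights and 29 without sh3. Depth limits genes of few reads, such as Bicd1 and Ifng.

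Signs turned for the following results, and no single gene among them was past the threshold. On the TPM scale they were Fas -0.073, Saa1 -0.062, Stab2 -0.038, type I interferon -0.009, endoplasmic reticulum stress -0.045, bile acid -0.073 and ribosomal -0.033. With size factors the medians were NRF2 0.025, fatty acid oxidation 0.071, cholesterol 0.031, fatty acid synthesis 0.014 and cholangiocyte 0.003. With quantile normalization they were Saa1 -0.226, fatty acid synthesis 0.022 and cholangiocyte 0.039. With array weights they were Fas -0.233, Mmp7 0.145, Saa1 -0.222, fatty acid oxidation 0.079, cholesterol 0.017, pericentral 0.035, endothelium -0.011 and red cell 0.334. Fatty acid oxidation was 0.012 at a mean FPKM of at least 5. Leaving out 1 library at a time gave ranges of -0.126 to 0.162 (Fas), -0.395 to 0.293 (Saa1), -0.672 to 0.220 (Socs3), -0.107 to 0.246 (Stab2), -0.267 to 0.015 (Tnfrsf1a), -0.045 to 0.195 (type I interferon), -0.190 to 0.349 (endoplasmic reticulum stress), -0.051 to 0.14 (bile acid), -0.083 to 0.109 (fatty acid oxidation), -0.349 to 0.269 (cholesterol), -0.175 to 0.088 (fatty acid synthesis), -0.326 to 0.087 (pericentral), -0.025 to 0.128 (ribosomal), -0.352 to 0.008 (Kupffer cell), -0.126 to 0.222 (endothelium), -0.556 to 0.171 (cholangiocyte) and -0.444 to 0.107 (red cell). The cause was not tested.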

Other observations

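The 9 gene families below were chosen after the data were seen, as were all tests here except those of gene length and GC content. Guanylate-binding protein genes, interferon-induced GTPases that act against intracellular pathogens, had a median log2 fold change of -0.51 with 9 of 10 negative (camera adjusted p = 0.0394; adjusted p = 0.484 with an estimated correlation). Their scores were -0.20, -0.23 and -0.34 in sh1, sh3 and sh6, against 0.12 to 0.49 in scramble, and the call was lost without Sc4 (adjusted p = 0.210) or sh6 (0.115). Collagen genes had a median of -0.26 with 11 of 13 negative (camera adjusted p = 0.0394; adjusted p = 0.977 with an estimated correlation), and the call was lost without Sc5 (median -0.16, adjusted p = 0.157) or sh6 (0.337). Both medians stayed negative on the TPM scale, with size factors and after quantile normalization, where the collagen median was -0.15. With all 6 libraries the other 7 families did not pass: the medians were -0.20 for major urinary protein genes, -0.83 for serpin A3 genes, -0.08 for replication-dependent histone genes, -0.03 for MHC genes, 0.03 for proteasome genes, -0.11 for cytosolic tRNA synthetase genes and -0.08 for SLC transporter genes. All of these medians but that of serpin A3 genes changed sign under another scaling or without 1 library. The shBicd2 libraries went apart in the major urinary protein genes, which share reads among close copies, with scores of -1.43 in sh1, -0.10 in sh3 and 1.16 in sh6 against -0.07 to 0.25 in scramble. This family passed as higher without sh1 (median 0.42, adjusted p = 6.15e-05) and as lower without sh6 (median -0.91, adjusted p = 0.00309). Serpin A3 genes, close copies too, scored -1.51 in sh1, 0.27 in sh3 and 0.11 in sh6, and their median without sh1 was -0.07.

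The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these 10 splits, 10 gave as many genes past the threshold as the real one, since the count is 0 in each. For genes at an unadjusted p below 0.05 the real split gave 1593 and the highest other 1059, so 1 of 10 gave as many. For lists past the threshold the real split gave 17 and the others 11 to 20, and 5 of 10 gave as many, the real one included. The number of lists past camera with its preset correlation therefore does not set the real groups apart from other groupings.

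The TNF, AP-1 and hypoxia lists were low in sh1 and sh6 and close to the scramble libraries in sh3. Relative to the scramble mean, their joint score was -1.81 in sh1, -1.29 in sh6 and -0.24 in sh3. Scaling between libraries is argued against. The median member, at -0.98, stayed at -0.91 (95% bootstrap interval over genes -0.99 to -0.83) under the scaling that moved it most towards 0. The TPM scale moved the median of each list away from 0, but it also raises all values against the pseudocount of 1. A pseudocount of 0.1 alone gave a TNF median of -1.11, against -1.12 on the TPM scale. The TPM scale also shifts the groups: the log2 fold change of Alb was 0.356 with either pseudocount and 0.261 on that scale. The effects of scaling and pseudocount were not separated. In sh1 there is only weak evidence against fewer neutrophils and monocytes as the whole source, with their pooled median marker at -0.17 (-0.70 to 0.27) against -1.48 for the 3 lists. The cell types went apart there: the neutrophil score of 0.01 lay below the scramble scores of 0.16 to 0.44, and the monocyte score of 0.27 within theirs. A part for fewer neutrophils in sh1 stays open. In sh6 the pooled markers were at -0.98 (-1.18 to -0.71) against -1.14, so fewer such cells are not argued against there. All intervals in this paragraph resample genes, which were correlated. The estimated correlation was 0.677 to 0.690 for the 3 lists, 0.391 for neutrophil and 0.586 for monocyte markers. The intervals are therefore too narrow and leave out the spread between livers. Which cells express the genes of the 3 lists was not tested, so a fall of similar size does not show that source. Animals that differed in their response to ConA, apart from the plasmid, cannot be told apart from the hairpin with 3 libraries: the score of sh3, which had the least Bicd2, was -0.24 from the scramble mean, and the lowest was -1.81.

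Mitochondrial transcripts were higher in shBicd2, with a median of 0.57. Removing the trend of nuclear genes with GC content left 0.64 (0.44 to 0.74), which argues against GC bias as the whole source. The mitochondrial transcripts have 31.9% to 41.1% GC, near the lowest nuclear value of 31%. The interval leaves out the uncertainty of the trend at that edge, and it resamples correlated genes (estimated correlation 0.353). A part for GC bias therefore stays open. Removing the trend with gene length left 0.47 (0.26 to 0.62), an interval too wide to exclude a part for length bias. Reads shared with nuclear copies were not tested, and neither was a biological explanation.

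Hepatocyte markers were higher and stellate cell markers lower in shBicd2. A lower share of all non-hepatocyte cells would lower the markers of each other type alike. The median sinusoidal endothelial marker lay above the median stellate marker by 0.45 (95% bootstrap interval 0.19 to 0.80), and for Kupffer cells the difference was 0.28 (-0.15 to 0.60). The endothelial difference rests in part on sh1, whose endothelial score was 0.31 against -0.20 in sh3 and -0.18 in sh6: without sh1 it was 0.27 (0.05 to 0.44), and the Kupffer difference 0.04 (-0.17 to 0.29). The endothelial interval stayed above 0 without any 1 of the 6 libraries. It resamples genes, which were correlated in the endothelial list (estimated correlation 0.452). It is therefore too narrow and leaves out the spread between livers. Of the 16 endothelial markers 10 were positive and 6 negative, among the latter Cdh5 (log2 fold change -0.83) and Pecam1 (-0.52). The stellate list was taken because it was low in these same data, which favours a difference of this sign. Apart from the endothelial list, the other tested non-hepatocyte lists had negative medians. These were neutrophil -0.59, monocyte -0.31, red cell -0.25, Kupffer cell -0.10 and cholangiocyte -0.07. The medians thus give only weak evidence against a lower share of all these types as the whole source. A part for it stays open, and a change in stellate cells themselves was not tested.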
